A study of Mus musculus with 64 samples.

How the data were processed

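Polyadenylated RNA of 64 individually sorted cells was measured. The cells came from microdissected dentate gyrus of transgenic mice aged 6 to 7 weeks that carry a red fluorescent reporter under control of the doublecortin gene (DCX-dsRed), and were captured on a microfluidic chip before library construction with Nextera XT, per the labels' protocols. The submitters' processing notes name Bowtie2 (a read aligner), RSEM (an abundance estimator) and the mouse build mm9, without versions or the order in which they were used. Each deposited file lists 30970 RefSeq transcripts with a gene symbol and a value. The column header calls the deposited values RSEM expected counts, but they sum to 999999 to 1e+06 in each cell, so the deposited values were read as TPM, length-normalised transcript abundances scaled to the same total in every cell. TPM are not counts, and no count model was fitted.

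Transcript values were summed per gene symbol. The 1037 transcripts without a symbol, which held 0.172% to 0.735% of a cell's TPM, were left out, and 48 symbols that had turned into numbers were replaced through the transcript accession with the RefSeq gene table of GRCm38. This gave 23313 genes, of which 15022 were above 0 in at least 1 cell. The reference assembly differs from the build in the processing notes, so it was used for names and transcript lengths and no coordinates are printed. Of the gene list members, Pkm2 was matched to Pkm, and Hbb-b1 was not matched and was left out. The Pearson correlation between any 2 cells lay between 0.332 and 0.613 (median 0.472), so no library was taken for a repeat of another.

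Depth was estimated from the low values. In each cell the value of 1 read was found for the transcripts of at least 1000 bases with a length in the reference (14777 transcripts), as the value at which TPM times effective length piles up. Of the values between 0.5 and 1.5 reads, 74.5% to 84.5% lay within 10% of 1 read (median 81.2%), against 20% if they were spread evenly. The estimate was tested on 3 simulated libraries, where the ratio of estimated to drawn reads was 1.00 to 1.01. A gene was called detected at 1 TPM or more. Intervals for shares of cells are exact Clopper-Pearson intervals at the 95% level and cover counting error only.

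The labels name 1 group and no animal, so the 64 cells were treated as 1 biological sample. No test was made between clusters of cells, and each p-value of a correlation describes these cells and not a population of animals. The cells were clustered by Ward linkage on the first 10 principal components of log2(TPM + 1) of the 1000 most variable genes among those detected in at least 10% of cells. The number of clusters, from 2 to 6, was the one with the highest mean silhouette. A cluster took the name of the identity list with the largest mean log2 difference from the other cells, provided that at least 3 of its markers were detected in at least 50% of the cluster. No doublet caller was run. A library was said to hold a second programme when its score for the marker list of another cluster reached the 25th percentile of that cluster's own cells, a rule chosen after seeing the data. The list for the granule-lineage-like cluster was the pan-neuronal one.

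The maturation index of a cell was the mean z-score of log2(TPM + 1) over the late granule neuron list minus that over the early neuroblast list (16 genes each). It was computed in the cells of clusters not named as glial, vascular, immune, ependymal or erythroid, with the genes detected in at least 25% of these cells. Each gene outside the index lists, and the score of each of 12 function lists, was tested against the index by Spearman's rho and Pearson's r with two-sided permutation tests (100000 shuffles, or all orders where there were 8 cells or fewer). Benjamini-Hochberg adjustment ran over all genes tested and over the 12 lists. The median rho of a list's members was placed among 10000 random lists of the same size matched on mean expression. The random lists were not matched on how far members vary together, so the percentile is a description and no test. Each r was repeated without the 2 cells farthest from the median. The gene test was tried on simulated data with the real means and SDs of 8310 genes in 20 cells: it called 99 of 100 genes made with a true correlation of 0.9, 56 of 100 made with 0.7, and 10 of the 8110 made with none. Both sets of related genes were in the same simulated data, which eases the adjustment for each. The shares called therefore overstate those to be had where few genes are related.

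Before the data were examined, the 12 function lists, the 2 index lists, 11 identity lists (pan-neuronal, dentate granule lineage, GABAergic neuron, Cajal-Retzius or mossy or pyramidal neuron, neural stem cell or astrocyte, oligodendrocyte precursor, oligodendrocyte, microglia or macrophage, endothelial or mural, ependymal or choroid plexus, and erythroid) and the rule for named genes were fixed. The rule takes Dcx and Prox1, and the 12 genes with the highest and the 12 with the lowest rho among those past an adjusted p of 0.05 outside the index lists. Those genes also need the same sign of rho against the late score alone and, turned, against the early score alone, and symbols that start with Gm and a digit or end in Rik are left out. It further takes the 2 members with the highest and the 2 with the lowest rho in each function list, and the 3 members detected in most cells in each identity list. Some genes that the rule takes are not reported here. Genes named outside this rule were chosen after their values were seen, and they are those that lead a cluster, the members of the index lists and the genes of the closing observations.

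The alternatives fixed beforehand were pseudocounts of 0.1 and 10, detection in at least 3 cells or in at least 50% of cells, the number of genes detected held constant, all 64 cells, median-of-ratios size factors, cells with at least 2000 genes, each other cluster of at least 6 cells, Pearson's r in place of rho, each index list alone and the first principal component as the axis. For the clusters they were 500 or 2000 variable genes, k-means, and 1 cluster more. For detection they were values above 0 and values of at least 10 TPM. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.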

Results

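The data are the transcriptomes of 64 single cells sorted for the DCX-dsRed reporter from the dentate gyrus, the hippocampal region where granule neurons are added in adult mice. Doublecortin (Dcx) is a microtubule-binding protein of newborn neurons, and the title of the series names neuronal maturation as the question. All cells form 1 group with no stage, treatment or animal named, so there are no biological replicates and no comparison between groups. Cells are called by the number in their labels. The estimated depth was 464874 to 4027936 reads per cell (median 1074822 reads), and 3535 to 7480 genes were detected (median 5179). The libraries fell into 2 depth classes with none between 1291948 and 1919670 reads. The classes nearly follow the cell number, since the deeper libraries are all among cells 1 to 24 and the shallower ones are cell 20 and cells 31 to 83, so they may be 2 batches as well. The deeper class held 21 cells with a median of 5227 genes and the shallower class 43 cells with a median of 5128 genes.

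The sorted cells fell into 3 clusters, of which the largest carried myelin transcripts. It held 33 of 64 cells (51.6%, exact 95% interval 38.7% to 64.2%) and was oligodendrocyte-like: Cnp, a gene of the myelin sheath, had a median of 6715 TPM there, and Mbp, which encodes myelin basic protein, 4245 TPM. A granule-lineage-like cluster of 20 cells (31.3%, 20.2% to 44.1%) had Prox1, the transcription factor that marks dentate granule cells, in 17 cells, Calb1, a calcium-binding protein of mature granule neurons, in 19, and Snap25, a synaptic vesicle fusion protein, at a median of 4648 TPM. A stem cell or astrocyte-like cluster of 11 cells (17.2%, 8.90% to 28.7%) had medians of 9800 TPM for the glycolytic enzyme Aldoc, 2519 TPM for the gap junction gene Gja1 and 1176 TPM for the glutamate transporter gene Slc1a2.

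The genes that set each cluster apart included Trf, Opalin, Ptgds and Mal in the oligodendrocyte-like cluster, Pcp4, Atp6v1g2, Hpca and Fam84a in the granule-lineage-like cluster, and Dhrs3, Acsbg1, Sdc4, Ntsr2 and F3 in the stem cell or astrocyte-like cluster. The mean silhouette was 0.262 with 3 clusters and 0.249 with 2. The deeper libraries made up 13 of the 33, 7 of the 20 and 1 of the 11 cells. With the 500 most variable genes there were 2 clusters, 33 oligodendrocyte-like and 31 stem cell or astrocyte-like cells, and no cluster was named granule-lineage-like.

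Programmes of different cell types were found together in many libraries. Snap25 and Ncam1, which act in vesicle fusion and in cell adhesion, were detected in 64 of 64 cells, and the median of Snap25 was 1532 TPM in the oligodendrocyte-like cluster. Ncam1 was at 10 TPM or more in all 64 cells, so its detection does not set the clusters apart. Over the 10 pan-neuronal markers the summed level in that cluster ranged from 169 to 7482 TPM (median 2493 TPM), against 2913 to 10068 TPM (median 5957 TPM) in the granule-lineage-like cluster. A second programme was present in 22 of the 64 libraries, namely in 15 oligodendrocyte-like, 5 granule-lineage-like and 2 stem cell or astrocyte-like ones. Of the 15, 11 reached the neuronal bound and 6 the astrocyte bound. The 42 other libraries were 18 oligodendrocyte-like, 15 granule-lineage-like and 9 stem cell or astrocyte-like.

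**Figure D1:**
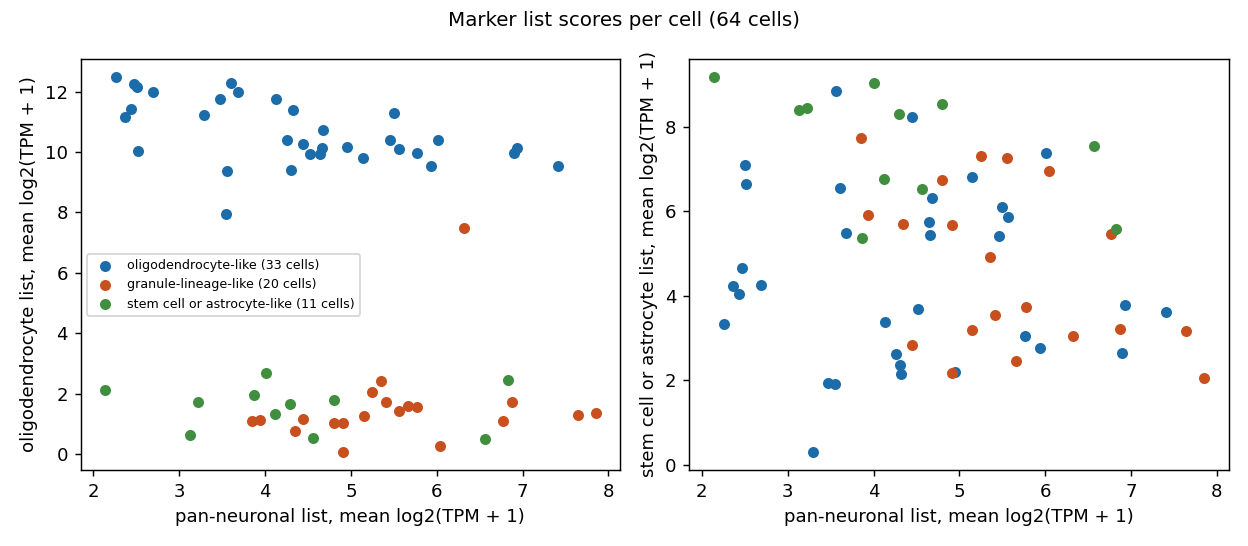
Each point is 1 of the 64 cells, coloured by cluster; both horizontal axes give the mean log2(TPM + 1) of the pan-neuronal list, and the vertical axes give that of the oligodendrocyte list (left) and of the stem cell or astrocyte list (right). Among the 33 oligodendrocyte-like cells the pan-neuronal score spreads widely, and 11 of them reach the lower quartile of the granule-lineage-like cells.

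Dcx, the gene whose promoter drives the reporter, was at 1 TPM or more in 24 of the 64 sorted cells (37.5%, 25.7% to 50.5%), with a median of 0.405 TPM and a highest level of 212 TPM. It was detected in 11 of 33 oligodendrocyte-like cells (33.3%, 18.0% to 51.8%), 6 of 20 granule-lineage-like cells (30%, 11.9% to 54.3%) and 7 of 11 stem cell or astrocyte-like cells (63.6%, 30.8% to 89.1%). Prox1 was detected in 41 cells (64.1%, 51.1% to 75.7%), with 21 of 33, 17 of 20 and 3 of 11 in the same order of clusters. A single read of Dcx was worth 0.161 to 1.62 TPM, and Dcx was above 0 in 40 cells and at 10 TPM or more in 9. The share with Dcx was 7 of 21 in the deeper and 17 of 43 in the shallower libraries (two-sided Fisher's exact test, p = 0.785). Without the 22 libraries that held a second programme it was 12 of 42.

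**Figure D2:**
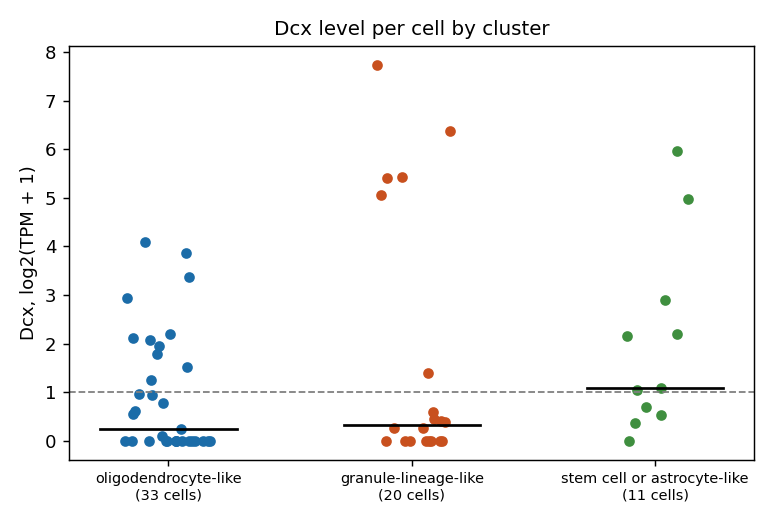
Each point gives the Dcx level of 1 cell as log2(TPM + 1) in its cluster, with a black line at the median and a dashed line at 1 TPM. In each cluster cells lie on both sides of the dashed line, with 24 of 64 cells at or above it.

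Among the neuronal markers of the granule lineage, Calb1 was detected in 50 cells, Stxbp6 in 48 and Neurod1, a transcription factor of granule neuron differentiation, in 46. Of 11 GABAergic markers, only Gad1, an enzyme of GABA synthesis, was detected in at least 50% of the cells (33 cells, median 1.70 TPM). Gad2 was found in 6 cells and Dlx6os1 in 4. Of the Cajal-Retzius, mossy or pyramidal list, Reln was detected in 16 cells, Wfs1 in 15 and Calb2 in 14. Of 9 oligodendrocyte precursor markers, Olig1 was detected in 49 cells, Sox10 in 40 and Gpr17, a receptor of committed precursors, in 28. Only 2 of the 9 were detected in at least 50% of the cells, and the least detected one was in 3 cells. The most often detected astrocyte markers, Aldoc, Gja1 and Slc1a2, were each present in 63 cells, and the myelin genes Mbp and Cnp were present in 56 and 55.

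Immune, vascular, ependymal and blood cells left few transcripts. Of 11 microglia or macrophage markers, 9 were in no cell, among them Aif1, and each count of 0 of 64 allows a share of up to 4.69% (3 counts of the total; the exact binomial upper bound is 5.60%). P2ry12 was detected in 4 cells. Of 12 endothelial or mural markers, 8 were in no cell, with Pdgfrb in 12 cells, Rgs5 in 4 and Tek in 2. Rarres2, Kl and Foxj1 of the ependymal or choroid plexus list were detected in 6, 5 and 2 cells, and Alas2, Hba-a1 and Hba-a2 of the erythroid list in 3, 2 and 0.

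Genes of early neuroblasts were sparse in the 20 granule-lineage-like cells, while genes of late granule neurons were common. The transcription factor gene Sox11 was detected in 20 of them (median 101 TPM), the cell cycle gene Ccnd2 in 14 and Nhlh2 in 5, and the remaining 13 genes of the early list in 4 cells or fewer. Of the late list, Camk2a, Ncald, Nrgn, Fam163b and Ryr2 were detected in 20 of 20 cells, with medians of 245, 954, 341, 138 and 30.6 TPM. The index therefore rested on 3 early and 14 late genes. Its early score spanned -0.843 to 1.13 and its late score -0.419 to 0.494, so the 3 early genes weighed heavily in it. Cell 61, with 3 early neuroblast genes detected, had the lowest index (-1.55). Cell 67, with 7 detected, had an index of -0.505. No relation of the early with the late score was detected across the 20 cells (Spearman's rho = -0.194, permutation p = 0.410; Pearson's r = -0.296, permutation p = 0.206). Without the 2 cells farthest from the median late score, r was -0.231 (permutation p = 0.354). The 2 scores were therefore not shown to oppose each other, so the index was not shown to order these cells by maturation. Relations along it describe the index only.

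Within the depth classes, with the index rebuilt in each, rho between the early and the late score was 0.107 (exact permutation p = 0.840) over the 7 deeper cells and -0.214 (permutation p = 0.482) over the 13 shallower ones. In the oligodendrocyte-like cluster, whose early score rested on Sox11 and Ccnd2, the scores rose together (rho = 0.426, permutation p = 0.0133; r = 0.412, permutation p = 0.0168; r = 0.408 without the 2 farthest cells; 33 cells). Within its depth classes rho was 0.495 (permutation p = 0.0878, 13 cells) and 0.355 (permutation p = 0.125, 20 cells). In the 11 stem cell or astrocyte-like cells rho was -0.0545 (permutation p = 0.881).

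**Figure D3:**
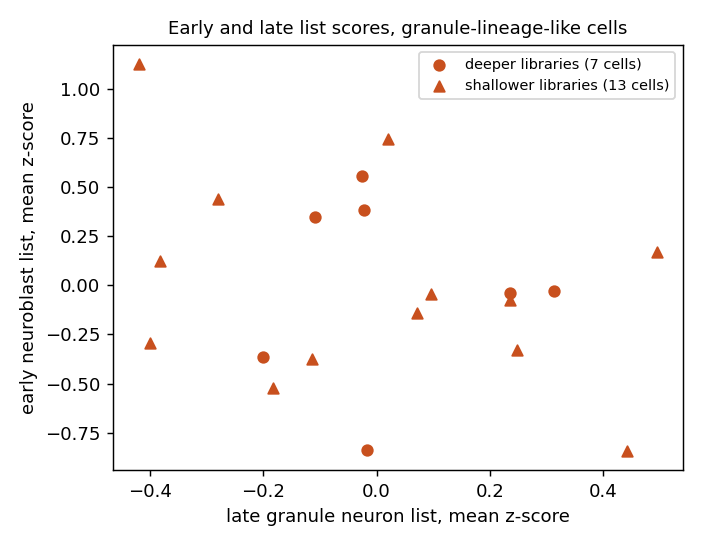
Each point is 1 of the 20 granule-lineage-like cells, with the mean z-score of the late granule neuron list on the horizontal and that of the early neuroblast list on the vertical axis; circles are the 7 deeper and triangles the 13 shallower libraries. Over these cells rho was -0.194 (permutation p = 0.410).

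No gene was found to change along the maturation index in the granule-lineage-like cells, which leaves open whether genes change with maturation itself. None of 8293 genes passed an adjusted p of 0.05 by Spearman's rho or by Pearson's r, with a permutation test and Benjamini-Hochberg adjustment, and the lowest adjusted p was 0.166. The smallest p the shuffles can give is 1e-05, so over 8293 genes a gene alone at that p could not pass. At an unadjusted p under 0.05 there were 450 genes by rho, 287 with a positive and 163 with a negative rho, and 436 by r. Against a null of 10000 shuffles per gene 453 genes lay under 0.05, and 18 of 100 shuffled indices gave at least as many (median 404.5 genes). Dcx had a rho of -0.481 (permutation p = 0.0337, adjusted p = 0.888; r = -0.308, permutation p = 0.186). Prox1 had a rho of 0.0421 (permutation p = 0.861, adjusted p = 0.995; r = 0.0234, permutation p = 0.921). The index had a rho of 0.263 with the number of genes detected (permutation p = 0.262; r = 0.269, permutation p = 0.254) and of -0.0165 with the estimated reads (permutation p = 0.948; r = -0.0107, permutation p = 0.965).

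None of the 12 function lists passed an adjusted p of 0.05 along the index. Voltage-gated ion channels had the highest rho, 0.481 over 18 genes (permutation p = 0.0339, adjusted p = 0.227; r = 0.417, permutation p = 0.0663; r = 0.474 without the 2 farthest cells), with 14 members above 0 and the median member rho of 0.0865 at the 78.8 percentile of matched random lists. Cacna1e and Scn1a, a calcium and a sodium channel gene, had rho values of 0.514 and 0.483, and Scn3b and the potassium channel gene Kcna1 of -0.172 and -0.397. Within the depth classes the list had a rho of 0.821 over the 7 deeper cells and of 0.451 over the 13 shallower ones, with exact or permutation adjusted p of 0.410 and 0.674. Its call depended on the setting, since it passed with the late list score alone as the axis (rho = 0.692, adjusted p = 0.0122) and with genes detected in at least 3 cells (rho = 0.717, adjusted p = 0.00660). The correlation fell to 0.0722 with genes detected in at least 50% of cells and to 0.236 without the libraries holding a second programme. The detection settings also changed the index itself. It held 8 early and 15 late genes with detection in at least 3 cells, and 2 and 13 with detection in at least 50%.

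Cytosolic ribosomal protein genes had the lowest rho, -0.438 over 31 genes (permutation p = 0.0551, adjusted p = 0.227; r = -0.406, permutation p = 0.0743; r = -0.521 without the 2 farthest cells). Of these, 23 lay below 0, and the median member rho of -0.186 stood at the 0.175 percentile of matched random lists. Members that vary together can give such a percentile more easily than the random lists allow for. Rpl7 and Rps9 had rho values of -0.668 and -0.615, and Rplp1 and Rps2 of 0.356 and 0.227. The list had a rho of -0.571 in the 7 deeper and of -0.423 in the 13 shallower cells, and it passed with genes detected in at least 3 cells (rho = -0.603, adjusted p = 0.0356). It weakened to -0.262 with genes detected in at least 50% of cells and to -0.268 without the libraries holding a second programme. Axon growth and cytoskeleton genes had a rho of -0.406 over 16 genes (permutation p = 0.0758, adjusted p = 0.227; r = -0.436, permutation p = 0.0552; r = -0.470 without the 2 farthest cells) and the 2.21 percentile. Stmn1, a microtubule-destabilising protein gene, and Tubb2b, a tubulin gene, had rho values of -0.626 and -0.533, and Mapt and Marcksl1 of 0.105 and 0.0898. Within the depth classes rho was -0.357 and -0.159, and with the late list score alone it was -0.205.

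Proteasome genes had a rho of 0.411 over 22 genes (permutation p = 0.0725, adjusted p = 0.227; r = 0.377, permutation p = 0.101; r = 0.376 without the 2 farthest cells), with 17 members above 0 and the 99.4 percentile. Psmc2 and Psmb2 had rho values of 0.421 and 0.361, and Psmb7 and Psma7 of -0.153 and -0.377. Within the depth classes rho was 0.393 and 0.280. It fell to 0.101 with the late list score alone, 0.167 with genes detected in at least 50% of cells and 0.243 without the libraries holding a second programme. Oxidative phosphorylation genes had a rho of 0.241 (permutation p = 0.305, adjusted p = 0.407; r = 0.425, permutation p = 0.0624), with Uqcrc1 and Ndufv1 at 0.575 and 0.537 and Cox7c and Ndufa1 at -0.235 and -0.424. Glycolysis genes had a rho of 0.247 (permutation p = 0.294, adjusted p = 0.407; r = 0.308, permutation p = 0.185), with Gapdh and Hk1 at 0.588 and 0.423 and Ldhb and Gpi1 at -0.227 and -0.378. Without the 2 farthest cells, r fell to 0.232 for oxidative phosphorylation and to 0.0727 for glycolysis.

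Of the synaptic lists, GABA receptors and chloride transport had a rho of 0.350 (permutation p = 0.132, adjusted p = 0.299; r = 0.123, permutation p = 0.608). Its member Slc12a5, a chloride exporter gene of mature neurons, had a rho of 0.356, and Gabrb1 and Gphn had rho values of -0.259 and -0.295. Glutamate receptors and postsynaptic scaffold genes had a rho of 0.335 (permutation p = 0.149, adjusted p = 0.299; r = 0.178, permutation p = 0.455). Here Grm5, a metabotropic glutamate receptor gene, had a rho of 0.653 and was the 1 gene of any function list past 0.05 when adjusted over the list alone, against 0 over all genes tested. Gria3 had a rho of 0.445, and Gria4 and Grin2a of -0.133 and -0.185. Synaptic vesicle release genes had a rho of -0.00301 (permutation p = 0.992, adjusted p = 0.992; r = 0.0141, permutation p = 0.953), with Stx1a and Syn1 at 0.408 and 0.368 and Rab3a and Cplx2 at -0.223 and -0.280.

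Immediate early genes had a rho of 0.289 (permutation p = 0.218, adjusted p = 0.373; r = 0.401, permutation p = 0.0795), which was 0.0239 for r without the 2 farthest cells. Their members Egr3 and Jun had rho values of 0.384 and 0.380, and Egr1 and Ier2 of -0.0136 and -0.361. The list passed with the late list score alone as the axis (rho = 0.606, adjusted p = 0.0338). RNA splicing genes had a rho of 0.0466 (permutation p = 0.847, adjusted p = 0.924; r = 0.0167, permutation p = 0.944), with Ddx5 and U2af1 at 0.648 and 0.286 and Hnrnpk and Sf3b2 at -0.245 and -0.514. Cell cycle genes had a rho of 0.0827 (permutation p = 0.729, adjusted p = 0.875; r = 0.10, permutation p = 0.672), with Ccne2 and Tyms both at 0.331 and Rrm1 and Pcna at -0.130 and -0.340.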

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

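The tests of the neuronal transcripts and of Dcx were chosen only after the result was seen, while those of the early and late scores were fixed before it. No sample group was of a size at which outlying cells are tested, no contrast was repeated between groups, and no data stayed outside the main measurement. No explanation that needs a comparison between groups was tested, since the labels give 1 group.

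Neuronal transcripts in the 33 oligodendrocyte-like libraries are the pattern most in need of a closer look, because the sort was for a neuronal reporter. The number of genes detected rose with the pan-neuronal score (rho = 0.721, permutation p = 1e-05, the smallest the shuffles can give; r = 0.652, permutation p = 9.0e-05; r = 0.674 without the 2 farthest cells), also within the 13 deeper (rho = 0.775, permutation p = 0.00288) and the 20 shallower libraries (rho = 0.597, permutation p = 0.00668). The summed TPM of the oligodendrocyte list fell as the pan-neuronal score rose (rho = -0.586, permutation p = 0.00037; r = -0.613, permutation p = 6.0e-05). A candidate explanation is that some libraries hold RNA of more than 1 cell, with the RNA of the oligodendrocyte diluted by that of a neuron. The 2 relations cannot single this out. A library with more genes detected can score higher on many lists, and no control list was tested. The values of a cell also share 1 fixed total, so a rise in some can lower others. Free RNA or reads shared between libraries stays open, since the summed pan-neuronal TPM differed 9.50-fold between the 90th and the 10th percentile, between the bounds of 3 and 10 that would have decided it, and a varying amount of free RNA would give the same 2 relations.

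Dcx was under 1 TPM in 40 of the 64 cells sorted for its reporter. Cells outside the granule lineage are argued against as the whole explanation, since 14 of the 20 granule-lineage-like cells also lacked Dcx at this level, a share with a lower 95% bound of 45.7%. The test takes it that granule-lineage cells hold Dcx, which was not examined. Calb1, a gene of mature granule neurons, was detected in 19 of these 20 cells. Depth stays open, since 33.3% of the deeper libraries had Dcx against 39.5% of the shallower ones (one-sided Fisher's exact test, p = 0.774), a difference within counting error between classes that may also be batches. A reporter protein that outlasts the transcript, and loss of transcripts during library construction, stay open and were not tested.

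Early and late scores rose together in the oligodendrocyte-like libraries (rho = 0.426, permutation p = 0.0133). The pan-neuronal score was then held constant, computed without Rbfox3 because that gene is also in the late list. The partial rank correlation was 0.126 (permutation p = 0.485), as it could be if the amount of neuronal RNA per library moved both scores. The late list is itself made of neuronal genes, so this fall cannot single out that explanation. Read depth alone is argued against, since the partial rank correlation was 0.384 (permutation p = 0.0266) with the estimated reads held constant. The number of genes detected, which rose with the pan-neuronal score in these libraries, was not held constant, so other differences in library quality stay open.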

How the results depend on the processing

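Settings chosen after the data were seen were the 2 depth classes, the estimated reads held constant, the granule-lineage-like and astrocyte-like clusters together, and the libraries without a second programme. The count of genes along the index stayed at 0 in 18 of 19 settings, and it was 133 when the granule-lineage-like and astrocyte-like clusters were joined (31 cells, 119 rising and 14 falling), a setting that also reads the difference between the clusters and in which 6 function lists passed. In every setting a gene alone at the smallest possible permutation p could not pass, least of all over the 7 deeper cells. The settings with 0 genes are therefore weak evidence that none changes. The lists that passed were 2 with detection in at least 3 cells and 2 with the late list score alone, for which the cause was not tested. With detection in at least 3 cells the index was rebuilt from 8 early and 15 late genes, so the axis changed as well. The setting of at least 2000 genes removed no cell. With 20 cells, 56 of 100 simulated genes with a correlation of 0.7 were called, beside 99 of 100 with 0.9 in the same simulation. That share overstates what would be called where few genes are related, so weaker relations were within reach only in part or less.

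With the 500 most variable genes 0 cells were granule-lineage-like and 31 stem cell or astrocyte-like. Of the 42 libraries without a second programme, 18 were oligodendrocyte-like (42.9%, against 51.6% of all) and 12 had Dcx (28.6%, against 37.5%), for which the cause was not tested. Dcx was above 0 in 40 cells and at 10 TPM or more in 9.

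The relation of the early with the late score kept its sign in 13 of 16 settings. It was 0.230 in all 64 cells, 0.426 within the oligodendrocyte-like cluster and 0.107 in the deeper libraries. Of the 12 lists, each short of the threshold, axon growth and cytoskeleton kept its sign in 19 of 19 settings (rho -0.664 to -0.118). The rho values of the other sign follow, and the cause was not tested. Synaptic vesicle release, at -0.00301 in the main setting, had 0.0141 with Pearson's r, 0.266 in all 64 cells, 0.50 in the deeper libraries, 0.0827 with detection in at least 3 cells, 0.646 with both clusters, 0.224 with the late score alone, 0.0767 with the genes detected held constant, 0.0301 with a pseudocount of 0.1, 0.391 and 0.0588 in the astrocyte-like and oligodendrocyte-like clusters, and 0.146 without a second programme.

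In all 64 cells the values of the other sign were -0.0345 for RNA splicing, -0.0946 for cell cycle, 0.0602 for ribosomal proteins and -0.233 for immediate early genes. Within the oligodendrocyte-like cluster they were -0.130, -0.0324, 0.0973 and -0.204 for the same lists, and -0.0117 for oxidative phosphorylation. Within the astrocyte-like cluster they were -0.00909 for RNA splicing, -0.482 for cell cycle, -0.473 for immediate early genes, -0.464 for oxidative phosphorylation and -0.536 for proteasome. With the early score alone they were -0.0195 for GABA receptors, -0.0180 for RNA splicing and -0.0647 for cell cycle. With the first principal component they were -0.409 for GABA receptors, -0.0331 for cell cycle, -0.402 for glutamate receptors and -0.0541 for ion channels. RNA splicing was at -0.0571 with detection in at least 3 cells and -0.108 with the genes detected held constant. With detection in at least 50% of cells, glutamate receptors were at -0.0211 and oxidative phosphorylation at -0.0496. Immediate early genes were at -0.214 in the deeper libraries, -0.278 with both clusters, where cell cycle was at -0.0613, and -0.0464 without a second programme. Glycolysis was at -0.192 in the shallower libraries.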

Other observations

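The genes in this part were chosen after their values were seen. Most of the cell cycle list was detected in 3 of the 64 libraries, 1 in each cluster. Cell 47, stem cell or astrocyte-like, had 24 of the 26 cell cycle genes detected, cell 67, granule-lineage-like, had 23, and cell 38, oligodendrocyte-like, had 22, while the next library had 9. Ccnb1, a cyclin of mitotic entry, was at 1187, 1277 and 1526 TPM in these 3 cells, and Top2a, a topoisomerase of dividing cells, at 567, 392 and 552 TPM. Top2a was at 1 TPM or more in no other cell. Each of the 3 also had 7 of the 16 early neuroblast genes detected, where the median cell had 2.5. Dcx was at 42.1 TPM in cell 67, at 0.440 TPM in cell 47 and at 0 in cell 38. Eomes, a transcription factor of intermediate progenitors, was at 230 TPM in cell 67 and 102 TPM in cell 47, and at 0 in cell 38, which had Hes6 at 261 TPM and Neurog2 at 22.4 TPM.

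Sox11, a transcription factor gene of newborn neurons, was at 1000 TPM or more in 7 cells that were spread over the 3 clusters, and 6 of these had Dcx at 1 TPM or more. The highest levels were 2829 TPM in cell 57, which also had Tubb3, the neuronal tubulin gene, at 1448 TPM and the astrocyte transporter gene Slc1a3 at 3115 TPM, and 2531 TPM in cell 67. Cell 80 had Sox11 at 1402 TPM, Neurod1 at 559 TPM and Slc1a3 at 3550 TPM. Cell 63, with Dcx at 212 TPM, had Sox11 at 1338 TPM and Calb1 at 523 TPM, and cell 2, with 11 early neuroblast genes, had Calb1 at 919 TPM. At least 5 early neuroblast genes were detected in 13 cells, of which 10 had Dcx.

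For genes outside those used to cluster the cells, list levels are given as mean log2(TPM + 1) over the members, with the SD between cells and no test between clusters. Oxidative phosphorylation genes were at 8.80 (SD 0.50) in the granule-lineage-like, 7.93 (SD 0.96) in the oligodendrocyte-like and 7.17 (SD 1.15) in the stem cell or astrocyte-like cells. Proteasome genes were at 8.30 (SD 0.51), 7.40 (SD 1.17) and 6.51 (SD 1.15), and cytosolic ribosomal protein genes at 9.16 (SD 0.36), 8.55 (SD 0.74) and 7.99 (SD 1.29), in the same order. The median number of genes detected had the same order (5501.5, 5227 and 4473). Immediate early genes were at 1.21 (SD 0.82), 0.84 (SD 0.56) and 1.49 (SD 0.76). RNA splicing genes were at 6.45 (SD 0.51), 5.55 (SD 0.69) and 5.81 (SD 0.69). The granule-lineage-like cells were highest in every function and index list except immediate early, cell cycle and early neuroblast genes. High levels in these cells were therefore not particular to the functions named here.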
